A study of Homo sapiens with 5 samples.

How the data were processed

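Single-cell RNA libraries of dermal fibroblasts under conversion were analysed, 1 per collection day, for days 0, 5, 10, 15 and 20. Per the labels' protocols, cells of each day were frozen until all days had been collected, and libraries were made with the 10x Chromium 3' chemistry. The authors deposited 1 matrix of raw UMI counts over all libraries, whole numbers per gene and cell with no normalization. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 3.1.4 were used with the human build hg38 (GRCh38). The authors' filter on cells is not given in the sources used here. The gene list held 32738 genes with older symbols, and its annotation release is not given in the sources used here, so no coordinates are printed. Whether this list belongs to the stated build was not checked. The matrix declared 3 more entries than it held. Cells were tied to days by the library name in each cell's name, where the library named for fibroblasts was taken as day 0 because only that sample's labels give no overexpression.

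Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept. Every deposited cell met the gene minimum, with 522 genes in the lowest, and 42, 21, 6, 2 and 5 cells of the 5 libraries exceeded the mitochondrial limit. Doublets were called per library with Scrublet in scanpy 1.11.5, and 4, 1, 3, 14 and 36 cells were left out, or 5.91% of the library labelled day 20. Because the caller marked under 0.5% of all cells, it cannot be taken to have worked, and results were also computed with doublets kept and with the 5% highest scores left out. The number called at the label day 20 was sensitive to numerical rounding, so numerical settings were fixed for a repeatable result. The kept libraries had median depths of 10906, 10996, 9977, 9361 and 8676 UMIs and median numbers of detected genes of 3674, 2924, 3201, 3354 and 3376 per cell.

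Counts were summed per library and divided by the library's total to give counts per 1e+06 UMIs (CPM). With 1 library per day there was no test, p-value or standard error. Levels carry exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, computed with scipy 1.17.1, and all cover counting error only. A count of 0 is given with the level that 3 counts would have, and a ratio against 0 counts is a lower bound against 3 counts over the library. For each of 50 gene lists, of which 663 of 667 members were found, the median log2 ratio of CPM with a pseudocount of 1 was taken over members with at least 10 CPM in at least 1 of the 2 libraries, a floor that a gene low in one passes only by being higher in the other. Its percentile among 10000 random lists of equal size, matched on mean expression in 20 bins, describes these libraries. List medians are given relative to the median of all genes over the same floor, and members are counted as higher or lower when 2-fold from that median. Some genes sit on several lists, as COL1A1, COL3A1 and FN1 do on the fibroblast and matrix lists. Counts of such lists partly repeat one another. TMM factors (edgeR 4.0.16 in R 4.3.3) were an alternative scaling, and directions of the summed G1/S level between labels turned under it.

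Genes were named by a rule: ISL1 and LHX3; up to 4 members of each list with the largest log2 ratio of day 20 against day 0; the 10 highest and 10 lowest genes of that comparison with at least 50 CPM; the 5 highest and 5 lowest of each successive step; and the top 5 genes by fold of each cluster. Mitochondrially encoded, ribosomal protein, HLA, sex-linked marker and unnamed transcripts were left out. The lists, the rule, the comparisons, the cell filters and the alternatives first listed were chosen before the data were examined.

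Log-normalised counts of 2000 variable genes were reduced to 30 principal components, and cells were clustered with 15 neighbours, Jaccard weights and the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5. No batch integration was applied, since each library is 1 day. Clusters were named only as neuron-like or cycling-like. The name required at least 3 fixed markers of that type 2-fold higher than in other cells, and exclusions applied. A cluster with enough markers lost the name when its leading genes held more markers of another type. It also lost the name when it was shallow for its library and none of its own markers was among its leading genes. This rule was settled after shares under a stricter one had been seen, and both are given; the Jaccard weights were adopted after a trial with fuzzy weights gave fewer clusters. Marker detection was compared after thinning each cell to 3000 UMIs without replacement, a depth set after the depths were seen. The comparison of the 2 largest clusters within a day and the lists used for it were chosen after the clusters were seen.

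Sites for miR-124 and miR-9 were counted in the longest 3' UTR per gene of the GENCODE 29 annotation. The log2 ratio of genes with each heptamer was compared with that of other genes by regression on UTR length and base composition, over 9490 genes and 16375 heptamers. The interval step was tested on Poisson counts simulated from a shared profile, for 10115 genes with 200 changed. Intervals covered between 91.3% and 94.7% of the set folds per fold size for day 5 against day 0 and between 90.0% and 100% for day 20 against day 0. The intervals assume this same model, so the coverage checks the computation and says nothing of spread between cells or libraries. For the labels day 0 and day 5, ratios were shuffled over genes and a heptamer effect was then planted. An effect of 0.3 log2 units ranked lowest in 20 of 20 draws, one of 0.1 in 5 of 20, and none in 0 of 20. Shuffling removes other sequence-linked differences, and among 16375 heptamers an unplanted one would rarely rank lowest. The draws therefore measure sensitivity and say nothing of specificity. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9 were used.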

Results

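The study followed the conversion of human dermal fibroblasts, the cells that make the collagen matrix of skin, toward motor neurons. Per the labels, lentivirus carried the brain microRNAs miR-9/9* and miR-124 together with ISL1 and LHX3, transcription factors of spinal motor neurons. Single-cell 3' RNA libraries were collected at days 0, 5, 10, 15 and 20, with 1 library per day. The day 0 label gives unconverted cells. The deposited table held 17101 cells, and after filtering 3119, 4359, 7159, 1762 and 568 cells remained in the libraries labelled day 0, 5, 10, 15 and 20. Their total depths were 34262995, 47528785, 74755167, 17639117 and 5325986 UMIs (unique molecular identifiers, each a counted RNA molecule). Median depth per cell lay between 8676 UMIs at the label day 20 and 10996 at the label day 5. With 1 library per day there was no replicate spread and no test between days. All intervals below are exact 95% intervals that cover counting error only, and each fold is a ratio of counts per 1e+06 UMIs (CPM) between 2 libraries, not between conditions.

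ISL1 (ENSG00000016082) and LHX3 (ENSG00000107187), the overexpressed factors, checked the labels and went against them. ISL1 had 90 UMIs in the library labelled day 0, or 2.63 CPM (2.11 to 3.23), and LHX3 had 181 UMIs, or 5.28 CPM (4.54 to 6.11). Neither gene had a UMI in the libraries labelled day 5 or day 10, where a count of 0 allows up to 0.0631 and 0.0401 CPM. At the label day 15, ISL1 had 11 UMIs (0.624 CPM, 0.311 to 1.12) and LHX3 had 2 (0.113 CPM, 0.0137 to 0.410). At the label day 20, the 2 genes had 2 and 1 UMIs. A 3' tag of a transgene can fall in vector sequence outside the annotated gene, and whether the constructs keep the native 3' end is not given in the sources used here. The absence of UMIs therefore checks little, whereas UMIs of both factors in cells labelled as unconverted do go against that label. Every library is accordingly called by its label, and each direction below is one between labels that these counts put in doubt.

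**Figure D1:**
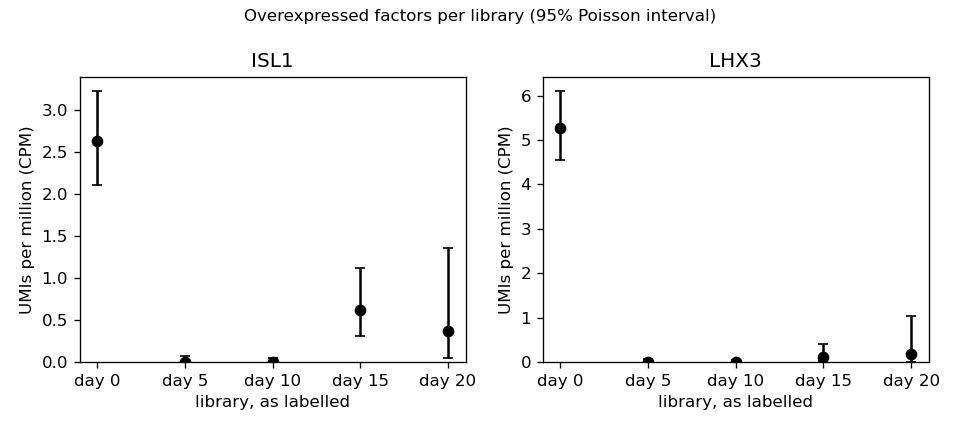
ISL1 and LHX3 in counts per 1e+06 UMIs, CPM (vertical axes) in each library by its day label (horizontal axes), with points for the summed counts and bars for exact 95% Poisson intervals. Both factors stood highest in the library labelled day 0, at 2.63 and 5.28 CPM, and at 0 in those labelled day 5 and day 10.

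Between the labels day 5 and day 0, COL1A1, the main collagen of skin, stood at 3523 against 874 CPM, 4.03-fold higher (3.98 to 4.08), and FN1, the matrix protein fibronectin, was 5.44-fold higher (5.37 to 5.50). The fibroblast marker S100A4 was 8.15-fold higher (8.02 to 8.28). COL3A1, another collagen, went the other way at 355 against 894 CPM. IFI6, an interferon-induced gene, was 29.8-fold lower (28.5 to 31.3), at 38.5 against 1149 CPM, and ISG15, the interferon-induced ubiquitin-like protein, was 15.2-fold lower (14.5 to 15.9). Because the all-gene median log2 ratio was -0.64 here, and moved by 0.64 under TMM scaling, list values are given relative to the all-gene median of their comparison throughout.

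Of the 15 measured fibroblast markers, 13 were at least 2-fold higher than the all-gene median and 0 at least 2-fold lower, with a relative list median of 2.57 log2 units, at percentile 100 of 10000 matched random lists. Of 28 matrix genes 22 were higher, with LOX, which crosslinks collagen, 3.39-fold (3.28 to 3.50), THBS1, thrombospondin, 3.66-fold (3.57 to 3.74) and COL12A1 4.51-fold (4.39 to 4.65) by CPM. Of 21 genes of caveolae and integrin adhesion 16 were higher and 1 lower, with the actin crosslinker FLNA 3.49-fold (3.36 to 3.63). The genes of this step with the largest ratios were the decoy receptor TNFRSF11B (osteoprotegerin), at 423 against 2.42 CPM, TM4SF20 at 57.9 against 0.525, IGFBP3, a secreted binder of insulin-like growth factors, at 9943 against 159, the matrix protein EFEMP1 at 272 against 4.84 and the protease inhibitor SERPINE2 at 4439 against 117. CTGF, a target of TGF-beta and YAP signalling, was 15.3-fold higher (14.8 to 15.9). The contractile gene TAGLN was 3.42-fold higher (3.36 to 3.48), within a myofibroblast list in which 6 of 7 members were higher. STMN2, a microtubule regulator of growing axons, stood at 107 against 5.60 CPM, although fewer than 3 members of the neuron list reached 10 CPM here.

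Of 14 interferon-response genes 12 were at least 2-fold lower than the all-gene median at the label day 5 and 0 were higher, with a relative median of -2.68. IFIT1 was 26.2-fold lower (22.6 to 30.4). Among 12 p53 targets 7 were lower and 0 higher, including the ribonucleotide reductase subunit RRM2B, 5.18-fold (4.90 to 5.48), and the death receptor FAS, 3.93-fold (3.70 to 4.17). Cholesterol synthesis had a relative median of -0.75, with 4 of 16 members lower and 2 higher, and the sterol desaturase SC5D was 10.1-fold lower (9.21 to 11.1). GCHFR, a regulator of the first enzyme of biopterin synthesis, stood at 4.27 against 146 CPM, and the histone gene HIST1H2BC at 4.12 against 137. Among 19 genes known as miR-124 targets, 13 were higher at the label day 5 than the all-gene median allows and 1 was lower. VIM, the intermediate filament of mesenchymal cells, was 3.39-fold higher (3.34 to 3.43), while CD164, also a target, was 3.93-fold lower (3.81 to 4.05). This is the direction of a loss of targets at the label day 0, whose ISL1 and LHX3 counts contradict its name. The target list shares VIM, LAMC1, CAV1 and ITGB1 with the fibroblast, matrix and adhesion lists. Its counts, here and in the later comparisons, are therefore not separate from theirs.

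Of the graph neighbours of cells labelled day 0, 90.5% had the same label, 9.47% the label day 10, which 42.2% of all cells carry, and 0.0235% the label day 5. Between the labels day 10 and day 0, the relative median was 0.56 for the fibroblast list (4 of 15 members higher, 0 lower) and 0.52 for the matrix list (6 of 27 higher, 0 lower), around an all-gene median of -0.23. FN1 was 1.91-fold higher (1.88 to 1.93) at the label day 10, S100A4 1.93-fold (1.90 to 1.97) and COL1A1 1.29-fold (1.27 to 1.30), while COL3A1 was 2.15-fold lower (2.12 to 2.19). IGFBP5, another binder of insulin-like growth factors, was 8.81-fold higher (8.46 to 9.17). Of the 8 heat shock genes 1 was at least 2-fold lower than the all-gene median and 0 higher, and the chaperone HSPA1A was 2.61-fold lower (2.47 to 2.76). Interferon genes had a relative median of -0.36, at percentile 0.01, with ISG15 1.57-fold lower (1.55 to 1.60). With the library labelled day 5 as the reference, the relative median of the fibroblast list turned from 0.56 to -1.75, so its direction rests on which library stands for unconverted cells.

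From the label day 5 to the label day 10, 12 of 15 fibroblast markers were lower than the all-gene median and 0 higher, with a relative median of -1.75, and of 28 matrix genes 19 were lower and 0 higher. COL1A1 was 3.14-fold lower (3.11 to 3.16), S100A4 4.22-fold (4.18 to 4.25), LOX 6.99-fold (6.77 to 7.21), SERPINE2 15.1-fold (14.9 to 15.3) and CTGF 11.3-fold (11.0 to 11.5). The 5 genes with the lowest ratios were TNFRSF11B, IGFBP3, TM4SF20, the hair keratin-associated KRTAP1-5 and the cell cycle regulator RGCC. TNFRSF11B stood at 8.96 against 423 CPM, KRTAP1-5 at 4.13 against 111 and RGCC at 2.25 against 64.2. Interferon genes were higher, 9 of 11 with 0 lower and a relative median of 2.23, as IFI6 was 21.2-fold higher (20.2 to 22.2) and IFIT1 17.0-fold (14.7 to 19.7). Among 12 p53 targets 6 were higher and 0 lower. HIST1H2BC was 36.3-fold higher (31.5 to 42.0), GCHFR 21.3-fold (18.5 to 24.6) and 7SK, a small nuclear RNA that restrains transcription elongation, 53.7-fold (41.0 to 71.8). Of 19 miR-124 targets 13 were lower and 0 higher. The all-gene median was 0.39, and TMM scaling moved it by -0.41. If the labels day 0 and day 5 were exchanged, this comparison would be one against unconverted cells.

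Between the labels day 10 and day 15, SNAP25, a fusion protein of synaptic vesicles, stood at 69.3 against 0.187 CPM, 370-fold higher (220 to 679), and SYT1, the calcium sensor of release, was 111-fold higher (68.5 to 192) at the later label. The kinesin KIF1A, which carries synaptic vesicle precursors, stood at 59.9 CPM against a single UMI (0.0134 CPM), a ratio of 4475 (802 to 176933). PCSK1N, an inhibitor of prohormone processing, was 200-fold higher (166 to 243), the lipoprotein APOE 116-fold (98.1 to 137) and the complement protease CFI 523-fold (274 to 1146). TAGLN was 68.2-fold lower (58.8 to 79.5), the hyaluronan-degrading KIAA1199 90.8-fold (63.9 to 134), the small heat shock protein HSPB7 21.7-fold (17.2 to 27.7), PSG4 20.4-fold (15.8 to 26.9) and the cardiac actin ACTC1 14.8-fold (12.3 to 17.8).

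In this step 8 of the 16 neuron markers found reached 10 CPM in either library. Of these 8, 7 were at least 2-fold higher than the all-gene median and 0 lower, with a relative median of 2.79. The list of microtubule and axon genes had 9 of 15 higher and 0 lower, with the axonal kinesin KIF5C 35.3-fold (28.5 to 44.3) and GAP43, a growth cone protein, 9.28-fold (7.98 to 10.8). Synaptic vesicle genes had 7 of 11 higher and 0 lower. Immediate early genes had 6 of 9 higher and 0 lower, including JUNB, 9.37-fold (8.90 to 9.88), and IER2, 7.25-fold (6.84 to 7.68). The median share of mitochondrial UMIs per cell also differed in this step, at 1.43%, 1.76%, 1.25%, 2.56% and 2.53% along the labels. Among cell cycle inhibitors 4 of 13 were higher and 0 lower, with CDKN2A (p16) 3.01-fold (2.82 to 3.21) and CDKN1C (p57) 19.2-fold (14.9 to 24.9). Fibroblast markers had 8 of 15 lower and 0 higher, with COL1A1 3.82-fold lower (3.72 to 3.93), and matrix genes 13 of 27 lower and 0 higher. TGF-beta and YAP response genes had 9 of 14 lower and 1 higher, with CYR61 8.48-fold lower (7.63 to 9.45). Of 19 miR-124 targets 9 were lower and 0 higher. The all-gene median was 0.12, and TMM scaling moved it by -0.33.

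Between the labels day 20 and day 0, the longest interval of the series, SNAP25 was 713-fold higher (360 to 1657) at the label day 20, at 167 CPM, SYT1 568-fold (220 to 2095), the cell adhesion-associated ITM2A 2065-fold against a single UMI (368 to 81816), BEX5 330-fold (166 to 769), and PCSK1N 157-fold (125 to 200). CYP26A1, an enzyme that clears retinoic acid, stood at 332 CPM against 0 UMIs, at least 3791-fold higher against a floor of 3 counts, and its relative CYP26B1 was 180-fold higher (134 to 246). KIF1A stood at 115 CPM, CFI at 84.7 and APOE at 198. TAGLN was 109-fold lower (71.8 to 173), the microfibril protein MFAP5 77.3-fold (54.1 to 115), the collagen COL8A1 29.8-fold (23.7 to 37.9), ECM1 28.3-fold (17.7 to 48.7), KIAA1199 34.2-fold (17.3 to 79.4), ACTC1 25.9-fold (16.9 to 42.0), the lysosomal glycoprotein CD68 23.1-fold (15.1 to 37.4), the oxytocin receptor OXTR 20.2-fold (13.4 to 31.9), the BMP antagonist GREM1 18.5-fold (13.8 to 25.5) and CYR61 17.5-fold (14.0 to 22.3).

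By group, 8 of the 16 neuron markers found reached 10 CPM in either library. Of these 8, 7 were at least 2-fold higher than the all-gene median and 0 lower, with a relative median of 4.25, at percentile 100. STMN2 stood at 222 CPM, 39.6-fold higher (34.0 to 46.4), and GAP43 at 60.5 CPM, 53.1-fold higher (38.0 to 76.1). Microtubule and axon genes had 12 of 17 higher and 2 lower, synaptic vesicle genes 7 of 11 higher and 0 lower, and neuronal ion channels 5 of 6 higher and 0 lower, including the sodium channels SCN1A, 206-fold (54.7 to 1736), and SCN9A, 15.3-fold (11.3 to 20.9). The microtubule list shares STMN2 and GAP43 with the neuron list, and the synaptic list shares SNAP25 and SYT1, so their counts partly repeat it. Axon guidance genes had 9 of 14 higher and 1 lower, with NCAM1 69.2-fold higher (33.6 to 165). The transcription factor ONECUT2, a miR-9 target and motor neuron marker, was 77.2-fold higher (31.3 to 246). Of 17 motor neuron markers only 3 reached 10 CPM in either library, and these were higher: STMN2, ONECUT2 and the guidance protein SLIT2 at 2.26-fold (1.99 to 2.57). With the library labelled day 5 as the reference, only 1 of 3 was at least 2-fold higher than the all-gene median, and 0 were lower. In all of these lists, a gene near 0 at the label day 0 passes the floor only by being higher at the label day 20. The counts therefore say nothing of the members under it. Of 4 markers of GABA or glutamate neurons over the floor, 1 was higher and 0 lower; the glutamate transporter SLC17A7 stood at 31.7 against 0.525 CPM and the GABA enzyme GAD1 at 14.3 against 6.68. CHAT, the enzyme that makes the transmitter of motor neurons, had 0 UMIs in all 5 libraries, which at the label day 20 allows up to 0.563 CPM; it was named after its values were seen.

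On the other side, 10 of 15 fibroblast markers were lower than the all-gene median and 2 higher, with a relative median of -1.59, and S100A4 was 9.19-fold lower (8.17 to 10.4), COL3A1 9.07-fold (8.32 to 9.91), COL1A1 7.20-fold (6.66 to 7.80) and FN1 5.15-fold (4.81 to 5.52). Matrix genes had 15 of 27 lower and 1 higher, and caveolar and integrin genes 11 of 21 lower and 0 higher, with FLNA 16.3-fold (11.4 to 24.2). The WNT antagonist DKK1 was 13.0-fold lower (11.0 to 15.5). Interferon genes were lower against the label day 0 in 9 of 14 members, with a relative median of -1.46, and higher against the label day 5 in 5 of 9 members, with 2 lower and a relative median of 1.70. Genes of the respiratory chain encoded in the nucleus had 6 of 20 higher and 0 lower, among them UQCRQ at 3.32-fold (3.21 to 3.44) and ATP5I at 2.98-fold (2.84 to 3.13). The metallothioneins MT2A, 19.0-fold (18.1 to 19.9), and MT1X, 12.5-fold (11.4 to 13.9), were higher, while the iron store FTH1 was 2.86-fold lower (2.83 to 2.89). With the library labelled day 5 as the reference, 15 of 15 fibroblast markers were lower and the relative median was -3.24, and 6 of 8 neuron markers were higher and 1 lower, with 3.59. The all-gene median was 0.07, and TMM moved it by -0.27.

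**Figure D2:**
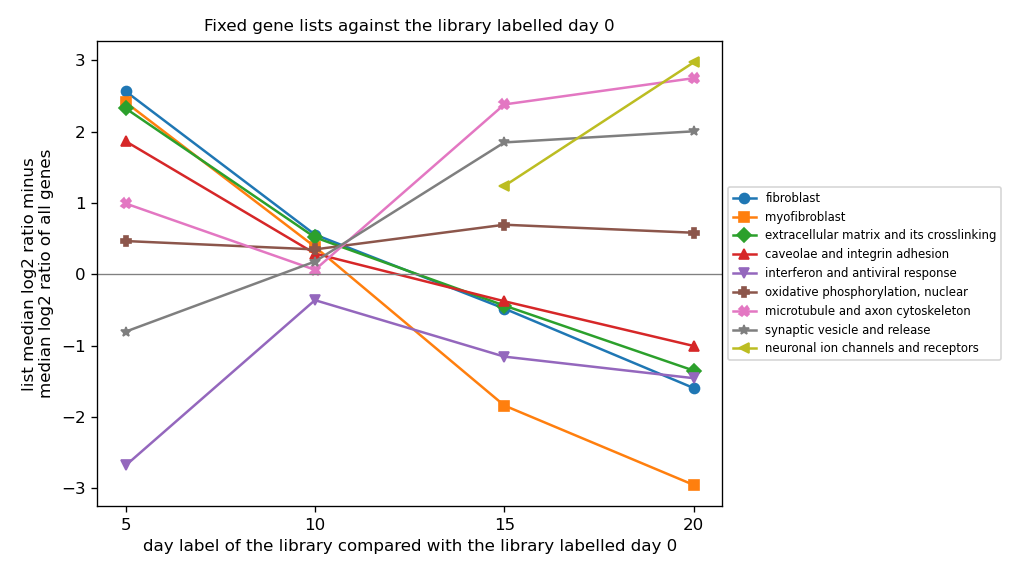
List median log2 ratio of the libraries labelled day 5, 10, 15 and 20 (horizontal axis) to the library labelled day 0, minus the median of all genes (vertical axis, log2), for 9 of the fixed gene lists, with a point where at least 3 members reached 10 CPM. The fibroblast list ran from 2.57 at the label day 5 to -1.59 at the label day 20, and the synaptic vesicle list from -0.80 to 2.00.

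Against the label day 0, SNAP25 was 297-fold higher (150 to 689) at the label day 15, where it stood at 69.3 CPM against 167 at the label day 20. STMN2 was 25.5-fold higher (22.0 to 29.7) and GAP43 27.6-fold (19.9 to 39.2). Of the 16 neuron markers found, 8 reached 10 CPM in either library, and 7 of these were higher than the all-gene median, with a relative median of 3.76. Axon guidance genes had 4 of 11 higher and 1 lower. The fibroblast list had a relative median of -0.48, with 4 of 15 lower and 2 higher. COL1A1 was 2.98-fold lower (2.89 to 3.07), FN1 1.68-fold (1.64 to 1.73) and TAGLN 44.7-fold (38.6 to 52.2). Against the label day 5 the same list had 14 of 15 members lower, with a relative median of -2.26. HES1, a Notch target that is also on the list of known miR-9 targets, was 6.94-fold higher (6.21 to 7.77) and MT2A 30.6-fold (29.4 to 31.9). Against the label day 0, 3 of 11 miR-9 targets were at least 2-fold higher than the all-gene median and 1 was lower. At the label day 20, 4 of 12 were higher and 2 lower, so against the label day 0 this list did not show the lower levels of the miR-124 list. Against the label day 5, 1 of 10 was higher and 3 lower at the label day 15. At the label day 20, 2 of 11 were higher and 3 lower against that reference. The miR-9 site itself ranked at 4.51% and 0.641% from the lowest of 16375 heptamers for the labels day 15 and day 20 against day 0. Interferon genes had 8 of 14 lower against the label day 0 and 5 of 9 higher and 2 lower against the label day 5. The list of the senescence secretome had 6 of 9 higher and 1 lower against the label day 0, including the chemokine CCL2 at 10.9-fold (9.97 to 11.9), and its median turned to -0.15 before adjustment against the label day 5.

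From the label day 15 to the label day 20, CYP26A1 was 8.44-fold higher (7.72 to 9.22), SYT1 2.63-fold (2.28 to 3.03), SNAP25 2.40-fold (2.20 to 2.62), ITM2A 2.33-fold (2.01 to 2.69) and BEX5 2.19-fold (1.93 to 2.48). MFAP5 was 11.0-fold lower (7.66 to 16.4), the dermal matrix protein DPT 9.21-fold (7.30 to 11.8), S100A4 5.57-fold (4.94 to 6.30), CCL2 5.43-fold (4.67 to 6.35) and ID1, a BMP target, 4.21-fold (3.33 to 5.41). The neuron list had 2 of 8 members at least 2-fold higher than the all-gene median and 0 lower, with a relative median of 0.57. Synaptic vesicle genes had 2 of 11 higher, microtubule and axon genes 1 of 17, axon guidance genes 1 of 14 and neuronal ion channels 0 of 6, with 0 lower in each. Fibroblast markers had 6 of 15 lower and 0 higher, with a relative median of -0.72. Matrix genes had 8 of 27 lower and 0 higher, and FN1 was 3.06-fold lower (2.85 to 3.29). The all-gene median was 0.16, and TMM moved it by -0.17.

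Clustering of all cells gave 17 clusters. Of the cells of cluster 2, 99.2% were labelled day 0, and of those of cluster 3, 99.7% were labelled day 5, so such a cluster can stand for a library as much as for a cell type, whereas cluster 14 drew 47.7% of its cells from its largest library. Cluster 2 held 77.5% of the cells labelled day 0, cluster 3 held 50.7% of those labelled day 5 and cluster 1 held 70.0% of those labelled day 10. Clusters 4 and 13, the neuron-like clusters, together held 95.8% (94.8 to 96.7) of the cells labelled day 15 and 94.9% (92.7 to 96.6) of those labelled day 20. They held 3 of 3119 cells labelled day 0 and none of those labelled day 5 or day 10, which allows up to 0.0688% and 0.0419%. SNAP25, APOE, CFI, PCSK1N and CYP26A1 led cluster 4, and RASD1, the neuropeptide CCK, ZFR2, 7SK and CYP26A1 led cluster 13. When a marker was also required among the top 10 genes of each named cluster, cluster 13 lost the name and the shares became 86.3% and 78.7%. At resolution 1.0 the neuron-like shares were 14.8% at the label day 15 and 73.1% at the label day 20, although the cluster that matched cluster 4 still held 1427 of the cells labelled day 15, against 1521. It was not among the named clusters at that resolution, so the share depends on the naming rule.

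Cluster 8, led by the proliferation genes MKI67, UBE2C, BIRC5, KIAA0101 and RRM2, was cycling-like and held 11.0% (10.1 to 11.9) of the cells labelled day 5 and 0 cells of the other 4 libraries. Under fuzzy neighbour weights its share at the label day 5 was 21.2%, and with 15 principal components it was 3.44%. Cluster 17, led by the interferon-induced genes IFIT2, OAS1, MX1, OASL and IFIT3, held 25 cells labelled day 0, 97 labelled day 10 and 0 of the other libraries. Cluster 14, led by the stress gene ATF3 and the clock gene NR1D1, and cluster 15, led by CLEC2A and the protease MMP3, had median mitochondrial shares of 0.211% and 0.0557%.

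**Figure D3:**
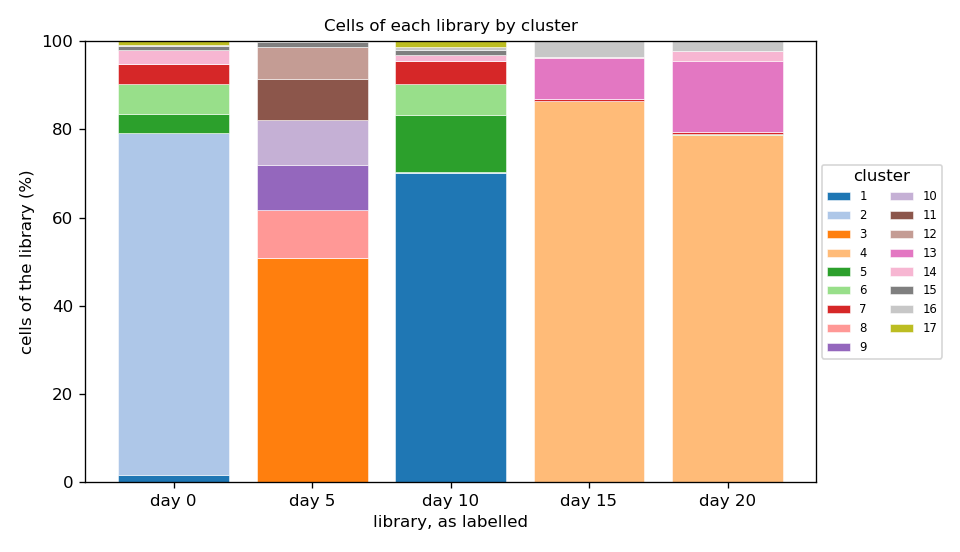
Share of the cells of each library (vertical axis, percent) in each of the 17 clusters (colours), by day label (horizontal axis). Cluster 4 holds 86.3% and 78.7% of the cells labelled day 15 and day 20, and no large cluster is shared between the labels day 0 and day 5.

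At an equal depth of 3000 UMIs per cell, SNAP25 was detected in 18.3% (16.5 to 20.3) of the cells labelled day 15 and 35.6% (31.6 to 39.9) of those labelled day 20, and in 0.0329%, 0.0235% and 0.0571% of those labelled day 0, 5 and 10. PTPRC, an immune gene taken as background, was detected in at most 0.373% of cells of any library, so SNAP25 at the 3 earlier labels lay at background. SYT1 was detected in 6.03% and 14.6% and GAP43 in 8.63% and 15.7% at the labels day 15 and day 20. STMN2 was detected in 1.78%, 15.7%, 5.90%, 30.6% and 42.5% of cells along the labels. S100A4 was detected in 55.8%, 99.8%, 77.8%, 53.2% and 12.9%, COL1A1 in 80.6%, 99.7%, 87.6%, 51.9% and 26.1%, FN1 in 77.9%, 99.7%, 93.7%, 65.3% and 33.0%, and COL3A1 in 75.5%, 60.4%, 60.3%, 27.4% and 19.6%. Cells under this depth were left out, 82, 111, 159, 71 and 32 in the 5 libraries. Without thinning the shares were higher, SNAP25 reaching 41.6% and 61.6% at the labels day 15 and day 20.

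**Figure D4:**
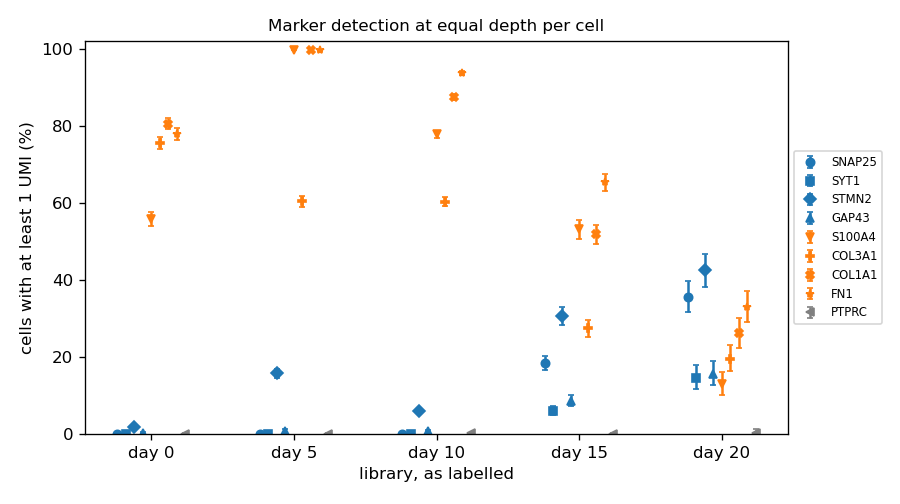
Share of cells with at least 1 UMI of each marker (vertical axis, percent) after thinning each cell to 3000 UMIs, by day label (horizontal axis), with exact 95% binomial intervals as bars. SNAP25 goes from 18.3% to 35.6% between the labels day 15 and day 20, while COL1A1 goes from 51.9% to 26.1%.

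The summed level of 20 G2/M genes, which act at cell division, was highest in the library labelled day 5, at 196 CPM (192 to 200), against 89.5 (86.4 to 92.7), 41.2 (39.8 to 42.7), 65.0 (61.3 to 68.8) and 84.7 (77.0 to 92.9) at the labels day 0, 10, 15 and 20. The 19 G1/S genes of DNA replication ran differently, at 225, 142, 176, 266 and 296 CPM along the labels. PCNA, the replication clamp, stood at 62.1, 20.8, 48.7, 91.4 and 99.7 CPM. With TMM scaling G1/S levels were 209, 209, 194, 230.5 and 227 CPM along the labels, so the lower level of the label day 5 than of the labels day 0 and day 10, and the higher level of the label day 20 than of the label day 15, are not kept under that scaling.

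In the libraries labelled day 5, 10, 15 and 20, conversion days by label only, the 2 largest clusters were compared in the summed levels of the neuron and fibroblast lists; the label day 0 was left out. In the cells labelled day 20, cluster 13 had 0.404 times (0.360 to 0.451) the neuron list level of cluster 4, and 0.347 times (0.323 to 0.372) its fibroblast list level. In those labelled day 15 the same ratios were 0.735 (0.683 to 0.791) and 0.403 (0.388 to 0.417). Among cells labelled day 5, the cycling-like cluster 8 had 0.446 times (0.419 to 0.474) the neuron list level of cluster 3 and 1.02 times (1.02 to 1.03) its fibroblast list level. Among those labelled day 10, cluster 5, led by the chaperone HSPA1A, had 0.811 times (0.780 to 0.844) the neuron list level of cluster 1 and 0.502 times (0.497 to 0.506) its fibroblast list level. The neuron list here includes UCHL1, a ubiquitin hydrolase abundant in neurons, which stood between 175 and 274 CPM in all 5 libraries and was named after its values were seen. The summed list stood at 455 CPM in cluster 3 at the label day 5 and 329 CPM in cluster 1 at the label day 10. UCHL1 can therefore make up much of the ratios at these labels. The clusters were also cut from the same counts, so some difference between them is built in, which the intervals do not measure.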

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

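Chosen after the data were seen were the reference labelled day 5, the 5% of cells with the highest doublet score left out, clusters of few mitochondrial UMIs or low depth left out, fuzzy neighbour weights and the marker rule on the top 10 genes. No paired analysis was possible because each day had 1 library. Of 768 alternative values of the results that answer the comparisons, 631 stayed within the counting interval or, for list medians, within an order-statistic interval over the list's members, which is wide; 137 moved out of it. List medians in this section are not adjusted for the all-gene median, unlike those of the results; unadjusted, the fibroblast list stood at 1.92, 0.33, -0.60 and -1.52 for the labels day 5, 10, 15 and 20 against the label day 0. Of 3880 values of the other lists, 3730 stayed, 143 moved and 7, whose median had been at least 2-fold, turned direction. Counting medians of any size, 231 of the 3880 changed sign: 50 of 115 with the reference labelled day 5, 53 of 270 each with TMM and median-of-ratios factors, and the others under the remaining settings. A shift that all genes share, as under another scaling or reference, can alone change the sign of a small unadjusted median. Under the alternatives listed in advance the neuron list median of the label day 20 against the label day 0 lay between 1.93 and 5.08, and the fibroblast list median between -1.95 and -1.49. For the label day 15 against the label day 0 the neuron list median lay between 1.27 and 4.45, around 3.64. Against the label day 10 it lay between 1.46 and 2.92, around 2.91. For the values below the cause was not tested, except where fewer UMIs per cell or a smaller list is the alternative itself. Depth limits the library labelled day 20 most, where 3 counts are worth 0.563 CPM. The caller marked under 0.5% of all cells as doublets and cannot be said to have worked, and the number called at the label day 20 was sensitive to numerical rounding; no list named above turned with doublets kept.

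Against the library labelled day 5 the unadjusted fibroblast list median was -1.36, -1.71 and -2.49 for the labels day 10, 15 and 20, the interferon list turned to 2.62, 1.57 and 2.44 at the same labels, and the senescence secretome list to -0.15 at the label day 15. At the label day 10, 27 of 38 list medians changed sign with this reference. The all-gene median also changed sign, from -0.23 to 0.39, so a small unadjusted list median can turn by this shared shift alone. With all detected members the senescence secretome list turned to -0.42 for the label day 5 against day 0 and 0.12 for day 10 against day 5. With members of at least 50 CPM the cycling list turned to -1.53 for day 5 against day 0, and the senescence secretome list to -0.50 for day 15 against day 10. The cycling value is that of the gene PCNA, whereas the summed G2/M level was higher at the label day 5, at 196 against 89.5 CPM.

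With TMM factors the fibroblast list median of the label day 5 against day 0 was 2.58, against 1.92 without them and by a shift that all genes share, and the summed cycling levels were 209, 209, 194, 230.5 and 227 CPM along the 5 labels for the G1/S genes and 83.2, 288, 45.4, 56.3 and 64.9 CPM along the 5 labels for the G2/M genes. With median-of-ratios factors that list median was 2.62 and the levels were 206, 212, 189, 235 and 229.8 CPM along the 5 labels for the G1/S genes and 81.8, 292, 44.2, 57.4 and 65.6 CPM along the 5 labels for the G2/M genes. As a mean over cells they were 137 and 182 CPM at the labels day 5 and 10 for the G1/S genes and 95.8, 171 and 42.8 CPM at the labels day 0, 5 and 10 for the G2/M genes. With every cell thinned they were 137 and 181 CPM at the labels day 5 and 10 for the G1/S genes and 95.05, 168 and 43.1 CPM at the labels day 0, 5 and 10 for the G2/M genes, and ISL1 and LHX3 at the label day 20 were 0 and 0 CPM.

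With 15 principal components the neuron-like shares at the labels day 0, 15 and 20 were 0%, 87.2% and 79.9%, and the cycling-like share at the label day 5 was 3.44%. Requiring a marker among the top 10 genes gave neuron-like shares of 0%, 86.3% and 78.7% at the same labels. Fuzzy weights gave 0% neuron-like at the label day 0 and 21.2% cycling-like at the label day 5. Resolution 1.0 gave 14.8% and 73.1% neuron-like at the labels day 15 and 20, and within-day cluster ratios of 0.406, 0.763 and 0.352 for the neuron list and 1.09, 0.640 and 0.400 for the fibroblast list at the labels day 5, 10 and 20. As a mean over cells the fibroblast list ratios were 1.04, 0.496 and 0.377 at those labels.

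Without thinning, the shares of cells with a UMI that moved were, in percent, 0.256, 0.275, 0.196, 41.6 and 61.6 along the 5 labels for SNAP25, 17.1 and 31.2 at the labels day 15 and 20 for SYT1, 3.98, 25.0, 12.1, 58.7 and 67.1 along the 5 labels for STMN2, 0.834, 2.34, 2.72, 23.3 and 32.9 along the 5 labels for GAP43 and 81.1, 99.95, 94.6, 82.4 and 31.2 along the 5 labels for S100A4. For the other markers they were 91.8, 92.0, 86.0, 52.3 and 37.9 along the 5 labels for COL3A1, 93.7, 99.9, 97.1, 82.1 and 54.9 along the 5 labels for COL1A1, 95.1, 99.9, 99.4, 88.6 and 59.5 along the 5 labels for FN1 and 0.289, 0.184 and 0.363 at the labels day 0, 5 and 10 for PTPRC.

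With thinning to 1500 UMIs they were 0, 8.85 and 21.3 at the labels day 0, 15 and 20 for SNAP25, 0, 0, 3.35 and 10.0 at the labels day 0, 5, 15 and 20 for SYT1, 0.962, 11.1, 3.27, 17.9 and 29.05 along the 5 labels for STMN2, 0.128, 0.459, 0.447, 4.82 and 7.57 along the 5 labels for GAP43 and 37.8, 98.3, 60.6, 34.2 and 6.34 along the 5 labels for S100A4. For the other markers they were 60.3, 38.8, 41.3, 13.9 and 10.0 along the 5 labels for COL3A1, 63.0, 97.2, 73.8, 31.7 and 13.6 along the 5 labels for COL1A1, 60.5, 98.0, 81.4, 44.0 and 18.7 along the 5 labels for FN1 and 0, 0.0698 and 0 at the labels day 5, 10 and 20 for PTPRC.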

Other observations

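The tests of carry-over, of depth, of absent or silent factors and of shallow cells were chosen after their results were seen. The tests on microRNA sites were chosen after list medians and some single targets had been seen, but before any site rank. Genes in the following paragraph that lie outside the naming rule (PTBP1, CTDSP1, ITGB1, CAV1 and MNX1) were chosen after their values were seen.

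The integrin ITGB1 stood at 125, 1530, 133, 45.9 and 49.2 CPM along the labels, the caveolar protein CAV1 at 132, 1680, 328, 94.8 and 74.5, the splicing repressor PTBP1 at 17.8, 48.3, 16.9, 15.9 and 17.5, and the phosphatase CTDSP1 at 8.96, 31.5, 9.31, 12.4 and 9.58. Of 8 hypoxia response genes 6 were at least 2-fold higher than the all-gene median at the label day 5 against day 0 and 0 lower, with VEGFA 3.21-fold (2.93 to 3.52) by CPM. The cell cycle inhibitor CDKN2A stood at 20.8, 40.4, 29.8, 89.6 and 127 CPM along the labels. Among immune markers CD14, a lipopolysaccharide receptor, was 30.4-fold higher (24.2 to 38.7) at the label day 20 than at day 0 while CD68 was 23.1-fold lower. MNX1, a motor neuron transcription factor, had 1 UMI at the label day 15, or 0.0567 CPM, and 0 at the label day 20, which allows up to 0.563 CPM, so the 2 labels are not ordered.

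ISL1 and LHX3 UMIs stood in the library labelled day 0 and not in that labelled day 5. Carry-over from another library of this series is argued against, since the highest LHX3 level elsewhere was 0.188 CPM against a lower bound of 4.54. A source outside these libraries was not tested. Lower depth is not the case, since the library labelled day 5 held 47528785 UMIs against 34262995 at the label day 0. There, 0 counts allow 0.0631 CPM at the label day 5. Correct labels with a microRNA response at day 5 are argued against as well: the miR-9 site ranked at 99.98% from the lowest of 16375 heptamers for the label day 5 against day 0. An exchange of these 2 labels may account for the pattern, as the miR-124 site ranked lowest of all for the label day 0 against day 5, at 0.00611%. The site also ranked lowest for the labels day 15 and day 20 against the label day 0, with adjusted differences of -0.13 and -0.15 log2 units. Against the label day 5 these were -0.43 and -0.45. A library labelled day 0 that was less exposed than the labels day 15 and day 20 would give the former under correct or exchanged labels. That the library labelled day 0 is another conversion day stays open, and the day itself, a difference that the design names, was not tested apart from the label.

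No ISL1 or LHX3 UMI was found in the library labelled day 10. Cells that never received the microRNAs are argued against, since for the label day 10 against day 5 the miR-124 site ranked lowest of the heptamers, at 0.00611%, with an adjusted difference of -0.29 log2 units, and the miR-9 site ranked at 0.0244%. This takes the label day 5 as the less exposed library. Against the label day 0, the library with UMIs of both factors, the 2 sites ranked at 86.4% and 98.4%, with a miR-124 difference of 0.02. Cells with the microRNAs in which the 2 factors are absent or silent cannot be told apart at 0 counts, which allow 0.0401 CPM, and transgene tags outside the annotated gene may give the same count.

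Clusters 14 and 15 had almost no mitochondrial UMIs. Nuclei that lost their cytoplasm are argued against, since the nuclear RNA MALAT1 was at most 1.12 times its level in other cells of the same libraries. Shallow cells are argued against, since their median UMIs were at least 1.14 times those of the other cells. Dying cells stay open and were not tested: in cluster 14, 7 of 12 p53 targets, 5 of 12 cell death regulators and 7 of 14 genes of the unfolded protein response were at least 2-fold higher than in other cells, with 1, 0 and 1 lower, and in cluster 15 none was 2-fold higher or lower. No biological explanation of these clusters was tested.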
